A study of Mus musculus with 4 samples.

How the data were processed

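The 4 libraries compared, 1 of each kind, came from inguinal white adipose tissue of male C57BL/6 mice aged 23 weeks that were obese from a high-fat diet: vehicle input, vehicle m6A immunoprecipitate (IP), entacapone input and entacapone m6A IP. Per the labels' protocols, poly(A) RNA was fragmented and part of it was pulled down with a polyclonal antibody against N6-methyladenosine (m6A), and TruSeq RNA libraries of the input and the IP were read on Illumina instruments. The labels do not say whether a library came from 1 animal or a pool. Per the submitters' processing notes, TopHat2 2.1.1 and MACS2, with the mouse assembly mm10, were used; the MACS2 version, the peak threshold, the tool that counted reads per gene and the annotation release are not given in the sources used here.

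The deposited values of each input library are raw read counts for 37315 Ensembl gene identifiers, with no normalization by the authors. The deposited values of each IP library are a peak list with a chromosome, a start, an end and an unlabelled number, read here as the authors' linear fold enrichment (a ratio of IP over input), because it never falls below 1 and its commonest values rise in equal steps. Whether starts count from 0 or from 1 is not stated, so coordinates are given as the deposited lists have them. The fold is the authors' value for that list and serves to describe, rank and filter peaks within a list. A ratio of the folds of shared peaks between the libraries was also computed, for all peaks and for 14 gene lists, and is left out of the results for that reason. Of those lists, 2 lay past the lower limit, lymphocyte and lymph node (percentile 0.465) and skeletal muscle (1.17), both with lower folds in the entacapone list. Those 14 remain in the 54 list comparisons counted below. A percentile of members with a peak in either list, against random lists matched on gene length, was also computed for 20 lists. Most of these lists lay past the limits, nearly all of them past the upper one. Random lists matched on gene length alone thus differ from these lists in how often genes carry a peak, which limits the length-matched percentiles given below. The percentile of members with a peak in either list does not compare the libraries and is not counted among the 54.

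Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3). A gene identifier entered with at least 1 CPM (counts scaled to library size) on average over both inputs, 13821 in all. The log2 ratio used a prior of 0.5 counts, and each ratio carries an exact conditional (Clopper-Pearson) 95% interval. An identifier is called higher or lower only when the whole interval lies beyond 1.5-fold. With 1 library per treatment there is no replicate, no test across samples and no p-value across genes; the intervals cover counting error only and compare these libraries, not the treatments. In simulated counts for the same 13821 identifiers with 200 changed ones, 92.0% of 2-fold and 100.0% of 4-fold changes were called and 0 unchanged identifiers were. The simulation drew counting error alone.

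Peaks were compared with bedtools 2.31.1, an overlap of at least 1 bp counting as shared. A peak was given the gene whose span in a RefSeq table of assembly GRCm38.p6, the assembly called mm10, holds its midpoint, with protein-coding genes first and the shorter gene where spans overlap. That table has neither strands nor exons, and it does not pair the Ensembl identifiers with names, nor do the count files. The counts are therefore described without gene names, with at most 2 identifiers in each direction, and the planned medians of gene lists in the input, the planned comparison of peak gain with input level and the planned filter of peak-bearing genes on CPM were not run. Peaks were placed by distance to the nearer end of the gene span, without regard to which end it is; exon, UTR and motif shares were not computed because no genome sequence was used. The planned threshold on a p or q value was not run, since the deposited lists have a fold alone.

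The 23 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 482 genes, of which 466 were matched by symbol, 6 of them by an older symbol; the 13 mitochondrially encoded genes lie on a chromosome absent from both peak lists. Lists with at least 5 peak-bearing members were set against 10000 random lists of genes with a peak, matched on the number of peaks in place of the planned mean expression, and the result is a percentile that describes these libraries. The matched number is that of vehicle-only and entacapone peaks together, so it includes the library-only peaks being counted. Genes that gained peaks are thus compared with genes of more peaks, which can absorb gains and shift the percentiles. Values under the 2nd or over the 98th percentile are reported as past the limits. The percentile for vehicle-only peaks was added after seeing the data, as was the chance that so many lists lie past the limits, which adds up each list's share of random lists past them and takes the lists as independent. Among 300 random lists, 2.0% lay past the limits, and 96.0% of lists built solely of genes with an entacapone-only peak passed the upper limit. Such lists hold the largest possible signal, so that share does not tell how lists with a weaker one would fare. The named peaks are, in each library, the 10 library-only peaks and the 5 shared peaks of largest fold within gene spans, 1 per gene, the peaks of Foxo1, Fto, Ucp1, G6pc, Lep and Adipoq, and up to 4 members of each list past the limits. Members named from the remaining lists are examples outside that rule. Most of them had more entacapone than vehicle peaks, so they do not represent their lists. A further gene of the rule is not reported here.

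Relative read depths were worked out from the steps of the folds, on the premise that MACS2 divides the IP reads plus 1 by the background plus 1 after scaling the larger library down. Scales put into simulated folds were recovered. Alternatives were other scalings (DESeq2 1.42.0 size factors, total counts, upper quartile), other CPM filters, a 2-fold threshold, a 99% interval, a fold of at least 4, 50% reciprocal overlap, a 100 bp window, equal numbers of top-ranked peaks and, for peak position, shared and library-only peaks apart. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.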

Results

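Entacapone, a drug used in Parkinson's disease and also described as an inhibitor of the m6A demethylase FTO, was given to mice made obese by a high-fat diet, and m6A peaks in inguinal white adipose tissue were compared with those of vehicle-treated mice. The data are 1 input library and 1 m6A IP library per treatment. The vehicle input held 24548212 gene-assigned counts over 20338 identifiers with at least 1 count, and the entacapone input held 33164576 counts over 21545 identifiers, 1.35 times as many counts. The 10 most counted identifiers took 13.2% of the vehicle counts and 13.6% of the entacapone counts. No library had a replicate, so every difference given here lies between these libraries, and counting intervals cover counting error only.

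Input RNA levels were compared to ask which transcripts differed in abundance between the treatments. Of 13821 gene identifiers with at least 1 CPM on average, 659 (4.8%) were higher and 447 (3.2%) were lower in the entacapone input with an interval wholly beyond 1.5-fold. The interval included no change for 6118 identifiers (44.3%). Large decreases outnumbered large increases: 48 identifiers were lower and 10 were higher with an interval beyond 4-fold, whereas beyond 2-fold 268 were higher and 189 lower. The log2 CPM of the inputs correlated across genes with r = 0.976, where genes are not independent replicates.

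The files do not pair these identifiers with gene names, so the extremes are given by identifier. ENSMUSG00000031710 had 24 counts in the vehicle input and 1211 in the entacapone input, or 1.01 and 35.4 CPM, a log2 ratio of 5.11 with a ratio interval of 23.4 to 54.9. ENSMUSG00000032496 had 22 and 731 counts, a log2 ratio of 4.50 with an interval of 15.1 to 37.0. In the opposite direction, ENSMUSG00000006764 had 807 counts in the vehicle input and 70 in the entacapone input, a log2 ratio of -4.04. ENSMUSG00000078672 had 295 and 26 counts, a log2 ratio of -4.00. Whether these differences hold in other animals has no replicate check.

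**Figure D1:**
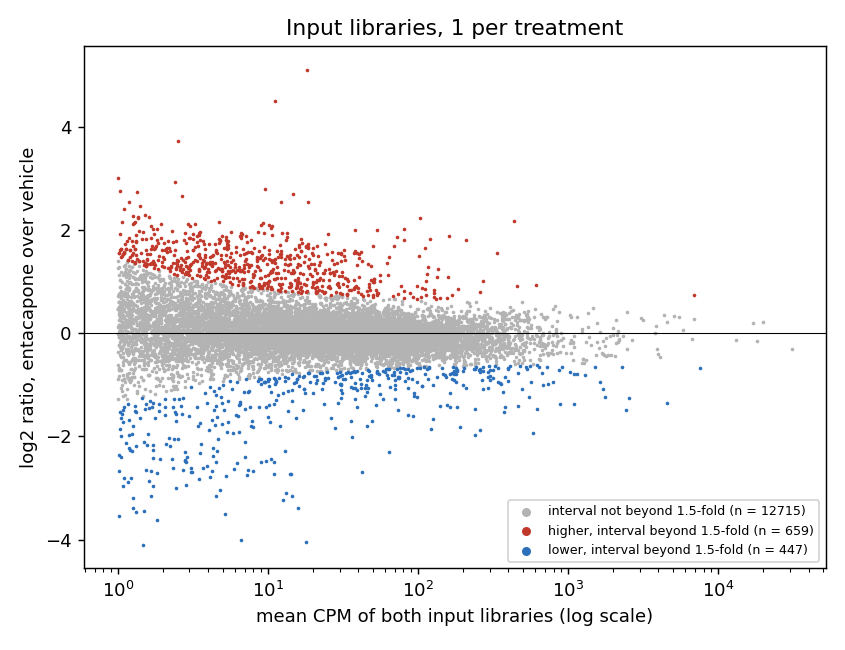
Each point is a gene identifier of the input libraries, with the mean CPM of both libraries on a log x axis and the log2 ratio of entacapone over vehicle on the y axis. Red points (659) and blue points (447) have a counting interval wholly beyond 1.5-fold; the remaining 12715 are grey.

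The m6A peak lists were compared to ask where the methylation signal differed. The entacapone list held 31856 peaks and the vehicle list 22860, a ratio of 1.39. Peaks with no overlap in the other list numbered 14059 for entacapone and 4858 for vehicle, a ratio of 2.89. Of the vehicle peaks, 18002 (78.7%) overlapped an entacapone peak, against 10.0% after the vehicle peaks were shifted by 1 kb. Of the entacapone peaks, 17797 (55.9%) overlapped a vehicle peak. At a fold of at least 4, 6231 entacapone-only and 4770 vehicle-only peaks remained, a ratio of 1.31.

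Peaks lay mostly in protein-coding genes. Protein-coding spans held 90.1% of vehicle and 89.1% of entacapone peaks, and 8804 and 10736 protein-coding genes carried at least 1 peak. Both lists shared 8268 of these genes, 2468 had a peak in the entacapone list alone and 536 in the vehicle list alone. The median peak was 115 bp wide in the vehicle list and 112 bp in the entacapone list, and the median fold enrichment given by the authors was 3.32 and 3.10, respectively.

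**Figure D2:**
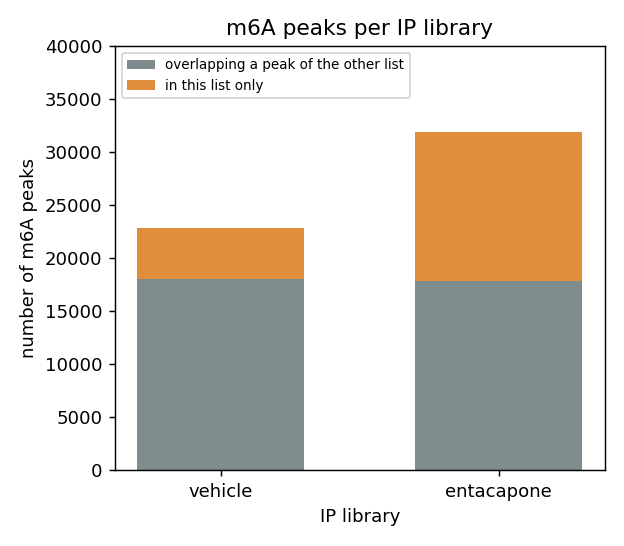
Bars give the number of m6A peaks (y axis) in each IP library (x axis), split into peaks that overlap the other list by at least 1 bp (grey) and peaks in that list alone (orange). The shared parts are similar, at 18002 and 17797 peaks, and the library-only parts are 4858 and 14059.

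Among genes named in advance, Foxo1, a transcription factor of the insulin response, carried 5 vehicle and 6 entacapone peaks on chromosome 3, with 4 of each shared. The Foxo1 peak of largest fold in the vehicle list lay at 52347161 to 52347254 (fold 2.99) and overlapped the one of largest fold in the entacapone list, at 52347146 to 52347270 (fold 3.16). The Foxo1 peaks in 1 list alone comprised 1 vehicle peak (fold 1.91) and 2 entacapone peaks (folds 1.60 and 1.79). Fto, the demethylase gene, carried 1 vehicle peak on chromosome 8 at 91313560 to 91313645, shared with the entacapone list, and 2 further entacapone peaks at 91409374 to 91409485 and 91666742 to 91666799. Lep, which encodes leptin, carried 2 peaks in each list on chromosome 6, all shared. No peak was listed in Ucp1, G6pc or Adipoq in either library, which does not show that the transcripts carry no m6A.

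A fold can be large because few input reads lie under the peak, and the planned filter on input level was not run. Peaks named for their fold may therefore lie in transcripts with little input. The next peaks named are the 10 library-only peaks of largest fold in each list, 1 per gene. In the vehicle list they were in AI987944 (chromosome 7, 41388153 to 41388221, fold 15.5), Traf1, a TNF receptor adaptor (chromosome 2, 34942918 to 34942989, fold 13.9), Zfp97, Pdlim3, Mylk4, Tbc1d14, Gucy1a1, Xpnpep3, Ccser2 and 4930444P10Rik, the last with a fold of 11.5. In the entacapone list they were in Anapc15-ps (chromosome 10, 95673379 to 95673465, fold 13.9), Slc23a2, a vitamin C transporter (chromosome 2, 132145029 to 132145083, fold 13.9), Kcna7, Immp2l, Gm16348, Gm7592, Rpgrip1, Gm4841, Cacng6 and Tubb4a, the last with a fold of 11.4. Among shared peaks within gene spans, those of largest fold in the vehicle list were in Lhx5 (chromosome 5, 120440733 to 120440816, fold 22.9), Mob1b, Zfp507, Nkx2-1 and Oscp1. Those of largest fold in the entacapone list were in Lonrf2 (chromosome 1, 38794470 to 38794535, fold 20.9), Nkx2-1, Rsu1, Rora and Shc4.

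Gene lists fixed in advance were used to ask which pathways and cell types carried the peaks. Of 22 lists with matched genes, 20 had more members with a peak in the entacapone list than in the vehicle list, 1 had equal numbers and 1 had fewer, in the setting of the 1.39-fold larger entacapone list. With the same number of top-ranked peaks from each list, 8 of 19 lists had more such members in entacapone, 4 had equal numbers and 7 had fewer, and at a fold of at least 4 these were 5, 4 and 5 of 14. The setting with the same number of peaks keeps every vehicle peak, 1837 of them under fold 2. It drops the entacapone peaks of lowest fold, including all 4330 under fold 2. Lists whose peaks have low folds can therefore lose entacapone members and gain vehicle-only peaks by construction. The member counts that follow are from all peaks. Genes of fat metabolism were among those with peaks in the entacapone list alone. The lipolysis list went from 6 to 12 of 14 members with a peak, with 0 vehicle and 1 entacapone peak in Lipe, hormone-sensitive lipase, and in Adrb3, the β3-adrenergic receptor, and 1 and 6 in Pde3b, a phosphodiesterase. Lipid synthesis went from 4 to 11 of 20, including Elovl6, a fatty acid elongase (0 and 4 peaks), and Acaca, acetyl-CoA carboxylase (1 and 4). The white adipocyte list went from 8 to 13 of 18, including Pparg, the adipogenic nuclear receptor (3 and 6), and Slc2a4, the insulin-responsive glucose transporter (0 and 2). Fatty acid oxidation went from 4 to 9 of 20, including Cpt1a, which starts mitochondrial fatty acid import (0 and 3). The thermogenic and beige adipocyte list went from 10 to 11 of 25, with 14 and 16 peaks in Prdm16, a brown fat regulator, and 2 and 6 in Ppargc1a. Some members went the other way: Adrb1 of the lipolysis list had 2 and 1 peaks, Npr3 of the white adipocyte list 5 and 3 and Gatm of the thermogenic list 1 and 0. None of these 5 lists lay past the percentile limits for entacapone-only peaks with all peaks and the number of peaks per gene matched. That number includes the entacapone-only peaks themselves, so this matching can hide gains. With the same number of top-ranked peaks the members with a peak in the vehicle and entacapone lists were 6 and 8 for lipolysis, 8 and 9 for white adipocyte, 4 and 7 for fatty acid oxidation, 10 and 10 for thermogenic and beige adipocyte and 4 and 10 for lipid synthesis. At a fold of at least 4 lipolysis and white adipocyte had 4 and 4 each, lipid synthesis 2 and 4 and thermogenic and beige adipocyte 5 and 9. With the same number of top-ranked peaks lipid synthesis lay past the upper limit (98.8), and with random lists matched on gene length instead lipolysis (99.9) and white adipocyte (99.8) did.

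Of 20 lists with enough members, 2 lay past those limits. All 11 peak-bearing members of the endothelial list had an entacapone-only peak, against a median of 8 in matched random lists (percentile 99.1). Endothelial members with any peak went from 5 to 11 of 12, or from 5 to 7 with the same number of top-ranked peaks, and Cdh5, the endothelial cadherin, had 0 vehicle and 5 entacapone peaks, Pecam1 0 and 4, Tek 0 and 3 and Vwf, von Willebrand factor, 2 and 6. The interferon response list had the opposite pattern: 3 of its 13 peak-bearing members had an entacapone-only peak, against a random median of 8 (percentile 0.08). Ifit1 had 7 vehicle and 4 entacapone peaks, Oas2 3 and 1, and Irf9 1 and 0, whereas Ifit3 had 2 and 3 and Rsad2 1 and 2. Vehicle-only peaks lay in 4 interferon members against a random median of 3 (percentile 66.9). The list thus stood out for few gains and not for losses. About 0.65 of 20 lists would lie past the limits by chance, counted from the random lists themselves, and 2 or more would with a probability of 0.136. The endothelial list was inside the limits with the same number of top-ranked peaks, at 96.6, and the interferon list with random lists matched on gene length, at 5.06. The remaining 18 lists lay between percentiles 6.22 and 97.6. With random lists of all protein-coding genes matched on gene length, which leaves expression unmatched, 9 of 20 lists lay past the limits for entacapone-only peaks. Nuclear oxidative phosphorylation was low (0.63) and 8 were high: endothelial, lymphocyte and lymph node, immediate early and stress, lipolysis, white adipocyte, nerve and Schwann cell, m6A machinery and fibroblast and extracellular matrix. For vehicle-only peaks the same matching put nuclear oxidative phosphorylation (0.37) and fatty acid oxidation (1.36) past the lower limit and the insulin and FOXO1 axis (98.2) past the upper. For vehicle-only peaks, 1 of 20 lists lay past the limits, the immediate early and stress list, with such peaks in 3 members against a random median of 7 (percentile 1.78), and it turned to 68.5 with the same number of top-ranked peaks.

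The m6A machinery list, which covers writers, erasers and readers, went from 16 to 20 of 23 members with a peak. Mettl3, the catalytic methyltransferase subunit, and Mettl14, its partner, had 0 vehicle peaks and 1 entacapone peak each, Alkbh5, the other known demethylase, had 1 and 2, and Zc3h13 had 11 and 10. With the same number of top-ranked peaks the m6A machinery list had 16 members with a peak in each library, and at a fold of at least 4 it had 8 and 5, past the limits for entacapone-only (1.29) and vehicle-only peaks (99.3), whereas random lists matched on gene length put it past the opposite limit for entacapone-only peaks (98.6). The insulin and FOXO1 axis list had 19 of 29 members with a peak in each library, with Irs1 at 7 and 10 and Irs2 at 6 and 7. With the same number of top-ranked peaks that list had 19 and 13 members with a peak and lay past the limits for entacapone-only (0.625) and vehicle-only peaks (99.7). Catecholamine handling went from 4 to 8 of 13, and from 4 to 4 with the same number of top-ranked peaks, with Maob, a monoamine oxidase, at 0 and 2. The circadian clock list went from 13 to 16 of 18, with Per2 at 3 and 8, and the immediate early and stress list went from 21 to 23 of 25, with Jun at 2 and 6. Both turned with the same number of top-ranked peaks, to 13 and 11 members for the circadian clock, with a vehicle-only percentile of 99.1, and to 21 and 17 for the immediate early and stress list. That setting drops low-fold entacapone peaks alone, so it cannot tell a turn from the unequal fold cut, here or for the insulin and FOXO1 axis.

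Lists of other cell types in the tissue gave macrophage 14 and 18 of 25, lymphocyte and lymph node 17 and 22 of 24, skeletal muscle 13 and 15 of 20, and fibroblast and extracellular matrix 8 and 17 of 22 members with a vehicle and an entacapone peak, respectively. Skin and gland epithelium gave 6 and 8 of 14, nerve and Schwann cell 6 and 9 of 10, erythroid 2 and 4 of 9, and cell cycle 10 and 12 of 18. Peaks were few in nuclear genes of oxidative phosphorylation, 1 and 7 of 47 members, and in cytosolic ribosomal proteins, 0 and 2 of 37. Inguinal fat can hold a lymph node and can be dissected with muscle, and markers of both carried peaks in both libraries, with Pax5, a B cell factor, at 4 and 9, Myh1, a fast muscle myosin, at 3 and 5 and Neb, nebulin, at 1 and 4. Myh4, another fast myosin, had 3 vehicle peaks and 0 entacapone peaks. With the same number of top-ranked peaks the members with a peak were 14 and 12 for macrophage, 17 and 15 for lymphocyte and lymph node and 13 and 10 for skeletal muscle, which turned these lists, and 8 and 10 for fibroblast and extracellular matrix, 6 and 8 for skin and gland epithelium, 6 and 8 for nerve and Schwann cell and 10 and 10 for cell cycle. At a fold of at least 4 fibroblast and extracellular matrix turned, to 6 and 4, as did cell cycle, to 6 and 5, and the lymphocyte and lymph node list had 9 and 3, with a vehicle-only percentile of 99.7. With matching on gene length that list had the opposite direction, with entacapone-only peaks in 16 members against a random median of 7 (percentile 100), and nerve and Schwann cell (99.7) and fibroblast and extracellular matrix (98.6) lay past the same limit. At that fold macrophage had 4 and 7, skeletal muscle 4 and 5, nerve and Schwann cell 4 and 6 and skin and gland epithelium 5 and 5.

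**Figure D3:**
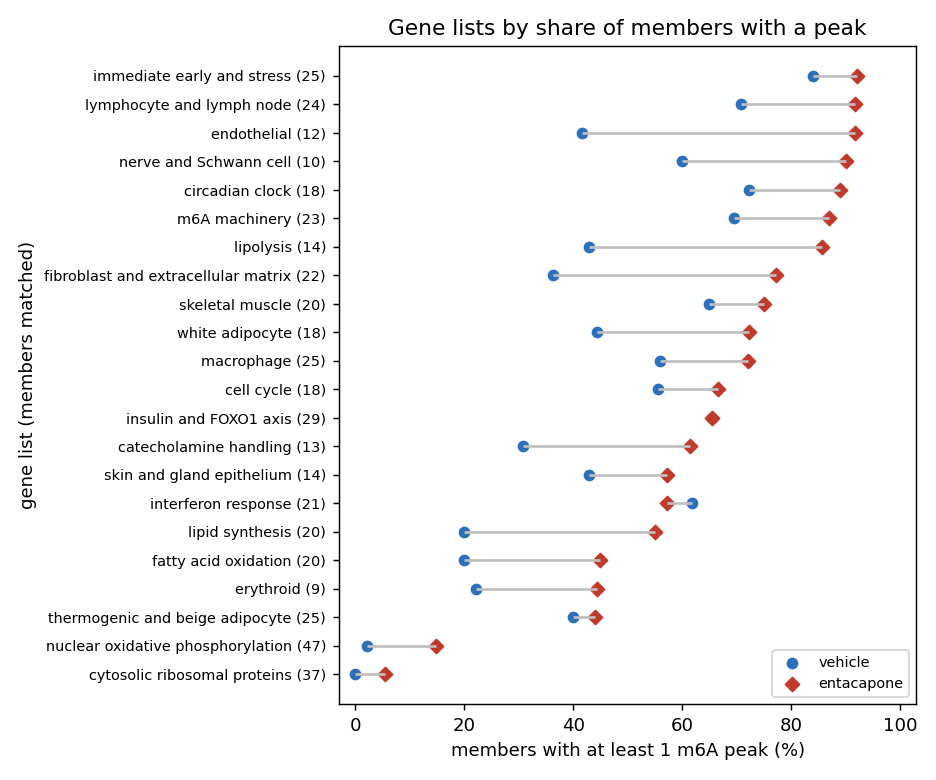
The x axis gives the percentage of matched members with at least 1 m6A peak in the vehicle (blue circle) and entacapone (red diamond) library, and the y axis gives each gene list with its number of matched members in brackets. The endothelial list moves from 5 to 11 of 12 members and the interferon response list from 13 to 12 of 21.

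In both libraries peaks lay near the ends of genes more often than random positions of the gene span did. Those positions were drawn over the whole span, introns included, because exons were not known. The excess therefore cannot be told apart from where exons and read coverage of poly(A) RNA lie, and is not read as a property of m6A. Within protein-coding spans, 26.9% of vehicle peaks (exact binomial 95% interval 26.3 to 27.5) and 28.0% of entacapone peaks (27.5 to 28.6) lay within 1 kb of the nearer gene end, against 11.7% and 11.9% for random positions in the same genes. Entacapone-only peaks lay there in 29.6% of cases, against 11.5% at random positions, and vehicle-only peaks in 26.6%, against 9.6%. With the same number of top-ranked peaks the entacapone share within 1 kb was 25.6%, below the 26.9% of vehicle. That setting drops low-fold entacapone peaks alone.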

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

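Peaks at least 100 bp wide, list matching on gene length, lists at a fold of at least 4 and families with equal numbers of peaks were chosen after seeing the data. Of 42 alternative values, 22 stayed within the margins, 15 moved, 3 came back inside the percentile limits and 2 turned to the other side. Counts of higher and lower identifiers were 646 and 460 with DESeq2 size factors, 774 and 348 with total counts, and within 1.5 times the reported numbers with the upper quartile, without a filter and with a 99% interval. They fell to 289 and 278 at 10 CPM, where fewer identifiers enter, and to 268 and 189 at 2-fold, a stricter threshold. Vehicle-only peaks numbered 9420 with 50% reciprocal overlap, 9525 with equal numbers of top-ranked peaks and 2986 with wide peaks alone; entacapone-only peaks numbered 6231 at a fold of at least 4 and 7774 with wide peaks alone. These settings take fewer peaks or ask for more overlap by their construction, and equal numbers of peaks force nearly equal numbers of library-only peaks, so that setting says nothing of the excess. The endothelial percentile was 96.6 with equal numbers of top-ranked peaks, the interferon percentile was 5.1 with lists of all protein-coding genes matched on length, and the vehicle-only percentile of the immediate early list was 68.5, 79.2 and, at a fold of at least 4, 9.3; the cause was not tested. At that fold the endothelial and interferon lists had too few peak-bearing members. Within 1 kb of a gene end lay 26.8% of shared, 29.6% of library-only and 25.6% of top-ranked entacapone peaks. Lists past the limits for entacapone-only peaks numbered 3 of 19 with equal numbers of peaks, 9 of 20 with length matching, which leaves expression unmatched, and 1 of 14 at a fold of at least 4. Input gene lists, peak gain against input level, CPM filters on peaks and p or q thresholds were not run, because identifiers are not paired with names and the lists give a fold alone. With 1 library per group, nothing could be left out in turn.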

Other observations

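The families and single genes in this paragraph were chosen after their values were seen. Zinc finger genes named Zfp carried a peak in 78.8% of vehicle and 82.1% of entacapone cases, against 40.2% and 49.1% of all protein-coding genes. Olfactory receptor genes named Olfr, rarely transcribed outside the nose, carried one in 4 and 5 of 1110. Genes of the mitochondrial ribosome went from 29 to 54 of 78 with a peak, cytosolic ribosomal proteins from 5 to 9 of 84 and proteasome subunits from 2 to 13 of 40. In a setting added after seeing the data, equal numbers of top-ranked peaks, the entacapone numbers were 21, 0 and 6, so both ribosomal families turned. That setting drops low-fold entacapone peaks alone, so such turns can follow from the unequal fold cut. Zfp genes stood there at 77.1% against 39.4% of all protein-coding genes. Among the 10 genes with the largest gain of library-only peaks in the entacapone list were Trdn, triadin of muscle (4 vehicle and 15 entacapone peaks), Akap12 (2 and 12), Ttn, titin (0 and 9), and Adamts5, a matrix protease (0 and 8). In the opposite direction stood Mki67, the proliferation marker (10 and 4), and Syne2 (7 and 2). With equal numbers of top-ranked peaks the entacapone numbers were 13 for Trdn, 2 for Akap12, 5 for Ttn, 3 for Adamts5, 4 for Mki67 and 2 for Syne2.

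The tests on peak number and on chance among lists were chosen after the result was seen, as was the pattern at gene ends; the remaining tests were written down before their value was known.

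The entacapone list held 1.39 times as many peaks. Relative depths were inferred from the steps of the fold values. The inferred scales explained 64.9% of the frequent vehicle values and 64.8% of the entacapone ones, against 0.0% at a typical scale. They put the entacapone input at 1.27 times, the IP at 0.98 times and the scaled depth at 1.22 times that of vehicle. The smallest number of IP reads commonly called over 0 input reads was 7 for vehicle and 5 for entacapone. Reads were recovered for 45.0% of vehicle and 37.7% of entacapone peaks, so ratios from recovered reads rest on unequal shares of the lists. Peaks of low background were compared next. Their entacapone to vehicle ratio was 1.35 as called and 1.11 with entacapone peaks rescaled to the vehicle depth. The limit on background, 5, was applied to entacapone peaks after rescaling in both cases. Entacapone peaks of somewhat higher background than vehicle peaks thus entered the first ratio, which raises it. A lower calling threshold may account for part of the excess in that set, which is a minority of the peaks. How large a part, these ratios cannot tell. The lower counting bound of the rescaled ratio, 1.07, leaves an excess. More m6A sites in the entacapone tissue cannot be told apart from a difference between single libraries. A uniform rise in m6A would be removed by scaling to library totals and was not testable.

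The endothelial list was rich and the interferon list poor in entacapone-only peaks. Matching random lists also on fold left the interferon percentile at 0.11. Fold, however, does not measure how readily a peak is called. Library-only peaks had higher median folds than shared ones, 3.84 against 3.19 for vehicle and 3.19 against 3.04 for entacapone. The matching therefore cannot decide whether strong peaks called in both lists are the cause. Input reads under shared interferon peaks, 1.12 times as many in entacapone (0.71 to 1.76), were too few to exclude fewer transcripts. For the endothelial list the same matching gave 99.11, and for the same reason it cannot decide on weak peaks called at the deeper scaling. Equal numbers of top-ranked peaks gave 96.6, inside the limits. Input reads under shared endothelial peaks were not compared, so more transcripts stay open. Chance over the lists may account for both: allowing for 54 list comparisons between the libraries, so extreme a percentile had a probability of 0.625 for the endothelial and 0.083 for the interferon list. Over the 20 lists of that comparison alone these were 0.305 and 0.032, and with random lists matched on gene length the interferon percentile was 5.06, inside the limits, so the reading of the interferon list depends on the matching and on how many comparisons are counted.

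Entacapone peaks were in particular excess close to gene ends: the ratio to vehicle was 1.64 within 200 bp (2611 and 1596 peaks) and 1.36, 1.33 and 1.39 in the 3 farther distance ranges, a ratio of ratios of 1.21 (counting interval 1.13 to 1.29) against peaks over 1 kb away. Short genes, whose peaks must lie near an end, are not the whole cause, since genes of 20 kb or longer gave 1.19 (1.08 to 1.31). After rescaling, low-background peaks gave 1.12 (0.96 to 1.31). That interval reaches 1, which met the rule written beforehand for weak peaks of the deeper scaling. These peaks showed no clear excess even as called, however, at 1.06 (0.91 to 1.23). On that account, a condition added to the written rule, the test decides nothing and weak peaks of the deeper scaling stay open. At a fold of at least 4 the ratios were 1.16, 1.03, 1.06 and 1.23 with distance, the highest being farthest from the ends. With equal numbers of top-ranked peaks, 25.6% of entacapone peaks lay within 1 kb of an end, below the 26.9% of vehicle. No biological explanation was tested, since the gene table gives no strand and the ends cannot be told apart.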
